A study of Mus musculus with 10 samples.

How the data were processed

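Total RNA of whole lung from 5 wild-type and 5 p53-null male mice was labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels' protocols. Signals were extracted with Agilent Feature Extraction 9.5, per the submitters' processing notes, and the deposited intensity is background-subtracted and detrended within each array, per the file headers. The deposited intensity values of the series' value table equalled those signals exactly (largest difference 0), so they are linear, not centred and not scaled between arrays; column medians ran from 250.0 to 452.

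From these, log2 intensities were scaled by each array's 75th percentile over 43379 non-control spots. Spots with outlier flags were left out, spots of a probe were averaged, and each gene was represented by its probe with the highest mean. Of 41174 probes, 22951 were named through accessions, 6659 through symbols and 3109 through synonyms in a table of the GRCm38 assembly used for names only; 8455 kept the file's name. Genes well above background on at least 5 of 10 arrays were tested, 21116 of 27670. Where a gene was not well above background on any array of a group, the fold is a bound, the bright group's mean against the dim group's mean of the higher of its own signal and the lowest signal well above background.

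Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The 28 gene lists were tested with camera at a preset inter-gene correlation of 0.01, and with an estimated correlation and fry as alternatives. Genes within 10 Mb of Trp53 were compared with all others by two-sided Fisher's exact test, with probe coordinates on mm7 from the files. Named genes were chosen by a rule fixed before the data were examined: Trp53; the 12 highest and 12 lowest called genes with a symbol whose 5 p53-null arrays lay on one side; and from each list up to 4 called members (8 for p53 target genes) by smallest p, or the 2 with the smallest p where none was called. A gene that this rule names is not reported here.

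Alternatives covered background, scaling, filter, probe choice, slide, slide number range, scan day, replicate number, variance model, array weights, thresholds and each array left out. Their values are given singly for every list that passed camera and for cytokines. Slides were recorded by number, and 1 slide held both groups, with wild-type array 4 and p53-null array 2. The higher slide number range held wild-type arrays 3 and 4 and p53-null array 2. Comparisons within either rest on 1 p53-null array, so their calls and p-values decide nothing. The lists were tested again under each of the alternatives except single-probe counting and the thresholds, where no list value was computed, and named genes were not evaluated with single-probe counting. Other groupings were examined in 100 of the 126 splits of the 10 arrays. The code was tested on simulated data: of 67 genes changed 1.5-fold among 20606, 38.8% were recovered. Of 67 changed 2-fold 61.2% were recovered, and of 66 changed 4-fold 92.4%, with 4 false calls in all. The simulated noise was independent between genes, without a shared array effect, GC trend or outlying array, so these shares need not hold for the real arrays.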

Results

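Gene expression was measured in whole lung of male mice, 8 weeks old, collected after 30 min of inhaled saline. Wild-type C57BL/6J mice were compared with mice lacking p53, the transcription factor encoded by Trp53 that induces cell-cycle arrest and apoptosis genes after DNA damage. Each genotype had 5 arrays, described in the series' design as separate biological replicates, with 1 RNA sample per array. Between 71.4% and 84.0% of spots were well above background, and the number of arrays limits the precision. All values are log2 differences, p53-null minus wild type, ± SE from limma with n = 5 per group and Benjamini-Hochberg adjusted p, unless stated.

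The targeted gene was examined first. A Trp53 probe printed in 10 spots, placed by the files on chromosome 11 from 69671206 to 69671265 (mm7), fell by 1.28 on the log2 scale (SE 0.16, limma adjusted p = 0.0123 over all probes). Its values lay between -3.15 and -2.66 on the p53-null arrays and between -1.67 and -1.43 on wild-type arrays 1 to 4, while wild-type array 5 read -2.22, between the groups. A second Trp53 probe, from 69662031 to 69662089, differed by 0.31 ± 0.28 (limma adjusted p = 0.613), with wild-type array 5 at 1.24. The unnamed transcript TC1467208, chosen after its values were seen, from 69665192 to 69665251 between them, was higher in p53-null lung by 3.35 ± 0.22 (limma adjusted p = 2.07e-04). Its values were -5.23 to -3.98 on wild-type arrays, with wild-type array 5 at -4.56, and -1.66 to -1.11 on p53-null arrays. The labels do not name the allele, and a probe outside the deleted part checks nothing.

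**Figure D1:**
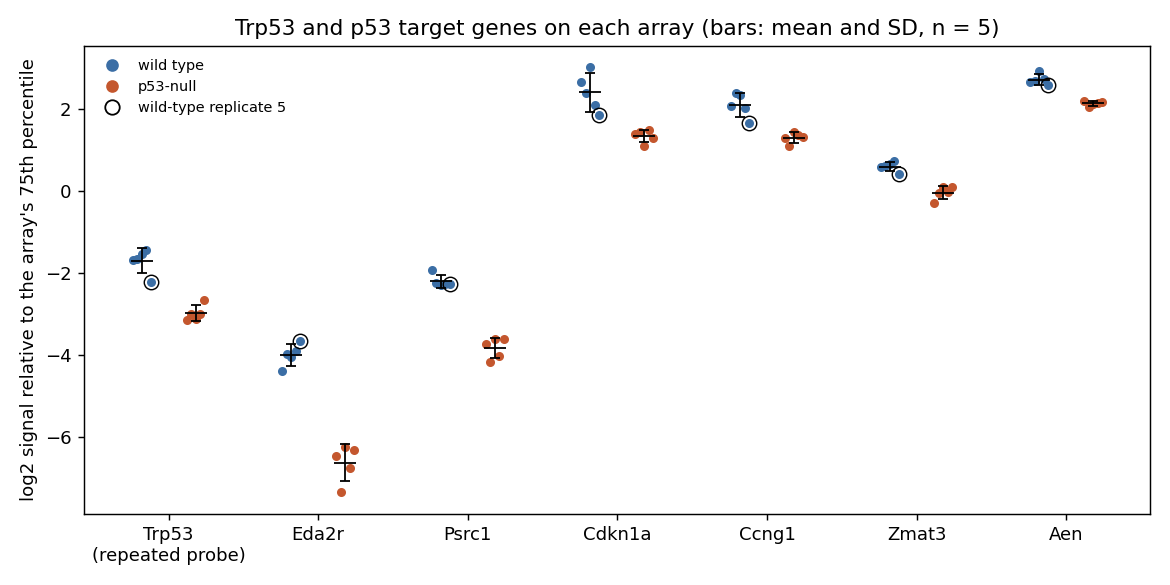
Log2 signal of Trp53 (probe in 10 spots) and 6 p53 target genes on each array, relative to the array's 75th percentile; points are arrays, bars mean and SD (n = 5), and the ring marks wild-type replicate 5. Eda2r and Psrc1 separate the groups on all 10 arrays, and wild-type replicate 5 reads -2.22 for Trp53.

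Several genes induced by p53 were lower in p53-null lung. The receptor gene Eda2r (-2.62 ± 0.22, adjusted p = 4.98e-04) and the spindle-associated gene Psrc1 (-1.62 ± 0.13, adjusted p = 4.51e-04) fell most. The cell-cycle inhibitor Cdkn1a fell by 1.07 on the log2 scale (SE 0.20), and Ccng1 (-0.80 ± 0.14), Zmat3 (-0.63 ± 0.096), Aen (-0.58 ± 0.079) and Phlda3 (-0.47 ± 0.10) also fell. Of 37 measured p53 target genes, 9 were lower and 2 higher over all genes tested, and 13 and 4 adjusted over the list alone. The genes that went the other way were the reductase Dcxr at 0.49 ± 0.12 and the phosphatase Ptprv, with mean log2 signals of -6.63 in wild-type and -4.63 in p53-null lung (adjusted p = 0.0418). The Aen probe is placed by the files on chromosome 4, and those on chromosome 7 gave -0.49 ± 0.11 and -0.31 ± 0.076; further Psrc1 probes gave -1.10 ± 0.12 and -0.77 ± 0.19. Eda2r was well above background on 4 p53-null arrays and Ptprv on 3 wild-type arrays. A further Dcxr probe differed by 0.11 ± 0.14. Dcxr, Ptprv, Phlda3 and Cdkn1a kept their call in 1, 2, 4 and 5 of the 10 fits that left out 1 array. The list's median was -0.21 (camera adjusted p = 2.84e-04, and adjusted p = 0.0833 with an estimated correlation). With the slide number range as a block the median was -0.19, and within the lower and higher ranges -0.14 and -0.19, the higher with 1 p53-null array. Under a fixed slide block, which compares 1 array of each genotype on the slide that holds both, it was -0.073, a smaller fall.

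Across the genome, 1581 of 21116 tested genes differed, 970 higher and 611 lower in p53-null lung. Among the 12 highest were Foxd4 (2.63 ± 0.28), Cuedc1 (2.47 ± 0.16), Gal (2.30 ± 0.23), Stfa2l1 (2.13 ± 0.28), Lep (2.03 ± 0.46), Trim30b (2.02 ± 0.27) and Med1 (2.02 ± 0.074); Gal encodes the neuropeptide galanin, Lep the adipocyte hormone leptin and Med1 a Mediator subunit. The other Med1 probes, also well above background on all 10 arrays, differed by 0.14 ± 0.11 and 0.27 ± 0.12, and a second Cuedc1 probe by 3.96 ± 0.12. Foxd4 and Lep were each well above background on 1 wild-type array, and Lep on 4 p53-null arrays. Mrgpra2b was not well above background on any wild-type array and was at least 2.59-fold higher in p53-null lung (adjusted p = 0.00473). Among the 12 lowest were Slfn5os (-3.92 ± 0.18), Fbxo39 (-3.22 ± 0.12), Slfn9 (-3.14 ± 0.24), Pitpnm3 (-1.44 ± 0.26), Meox1 (-1.39 ± 0.089), 6330403K07Rik (-1.36 ± 0.11) and Sp6 (-1.34 ± 0.19), all on chromosome 11, with Impg2 (-1.28 ± 0.19), Tmem252 (-1.24 ± 0.32) and Sele (-1.14 ± 0.28); Sele encodes the endothelial adhesion molecule E-selectin. Slfn5os and Slfn9 were each well above background on 1 p53-null array, and Impg2 and Sele on 3; the sizes of these differences and those of Foxd4 and Lep rest on signals near background. Lep, Tmem252, Sele and Pitpnm3 kept their call in 3, 2, 2 and 9 of the 10 fits that left out 1 array. Fold changes of 2 or more were found for 197 higher and 34 lower genes. The count moved with single arrays: it was 6619 without wild-type array 5 and fell to 192 without p53-null array 3, and every other array left out gave between 322 and 966. Higher and lower calls numbered 3604 and 3015 without wild-type array 5, and with the GC trend of probes also removed, an alternative chosen after seeing the data, lower calls were more frequent (2687 higher, 3234 lower). The count was 697 with the slide number range as a block and 16 by limma within the lower range (unadjusted p under 0.05 for 2565 genes). The higher range holds 1 p53-null array, so calls there decide nothing. Wild-type array 3 was the only array of its scan day, so the scan day block gave the same 322 calls as leaving that array out. Skeletal muscle genes stood high in wild-type array 2 and p53-null arrays 4 and 5, with scores of 3.83, 3.01 and 2.65, and 10 genes were called without these 3 arrays, a set chosen after seeing the data.

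Genes around Trp53 were called more often than genes in the rest of the genome. Within 10 Mb on either side, 51 of 418 genes were called (12.2%), against 1506 of 20313 elsewhere (7.41%). The odds ratio was 1.74 (95% interval 1.26 to 2.34, two-sided Fisher's exact test p = 6.66e-04). The excess was not confined to this window: over all of chromosome 11, 196 of 1698 genes were called (11.5%). Outside the window, from 80 to 90 Mb, 34 of 160 were called (21.25%). From 0 to 50 Mb, shares in bins of 10 Mb lay between 4.35% and 13.3%. Among 493 windows across the genome the highest share called was not near Trp53 but on chromosome 5 from 50 to 70 Mb (18 of 86, 20.9%). Windows on chromosome 11 from 80 to 100 Mb (17.5%) and on chromosome 17 from 30 to 50 Mb (15.4%) also ranked above the one from 65 to 85 Mb that holds Trp53 (14.8%). Of the 20 genes with the smallest p, 14 lay on chromosome 11, Med1, Fbxo39, Slfn5os and Cuedc1 among them. Without wild-type array 5 the odds ratio was 1.15 (Fisher's exact p = 0.183), and with each other array left out it lay between 1.87 and 4.41 (highest Fisher's exact p = 0.00128). It was 8.24 at adjusted p under 0.01 and 21.0 among the 10 genes called without wild-type array 2 and p53-null arrays 4 and 5.

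**Figure D2:**
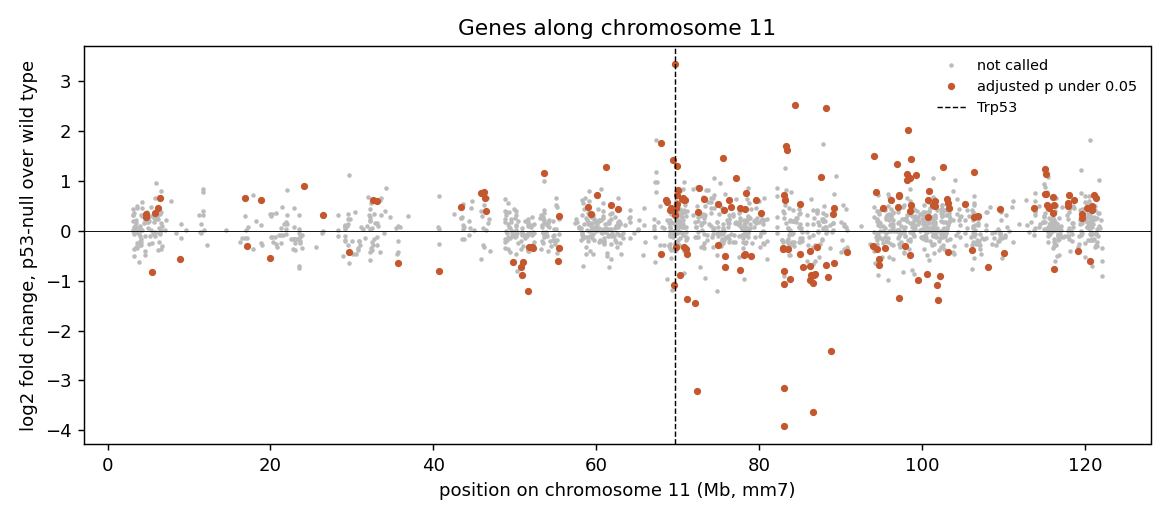
Log2 fold change (p53-null over wild type) of each tested gene against its position on chromosome 11 in Mb (mm7); filled points are genes past adjusted p 0.05, grey points the rest, and the dashed line is Trp53. Slfn5os at -3.92 and Fbxo39 at -3.22 lie to the right of Trp53.

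Many markers of neutrophils, B cells and T and NK cells were higher in p53-null lung. Of 13 neutrophil genes 7 rose (8 adjusted over the list alone), among them the calprotectin subunit S100a9 at 2.42 ± 0.28, the receptors Csf3r (2.10 ± 0.33) and Cxcr2 (2.06 ± 0.37), and the proteases Mmp9 (1.35 ± 0.16) and Mmp8 (1.11 ± 0.16). Of 12 B cell genes 7 rose (11 adjusted over the list alone), including Pax5 (1.72 ± 0.29), Ighm (1.25 ± 0.25) and Cd79b (1.17 ± 0.24). Of 18 T and NK cell genes 7 rose (11 adjusted over the list alone), including the T cell receptor component Cd3g (1.14 ± 0.19) with Cd8b1 (1.10 ± 0.22) and Thy1 (0.65 ± 0.11). A second Cd8b1 probe, placed by the files on chromosome 5, went the other way at -0.43 ± 0.10, and a second Thy1 probe gave 0.42 ± 0.28. A further Ighm probe gave 1.30 ± 0.70. Another, not well above background on any wild-type array, was also higher in p53-null lung, by an amount that was not sized. Cd8b1, Ighm, Cd79b, Pax5 and Thy1 kept their call in 5, 6, 6, 9 and 9 of the 10 fits that left out 1 array. The neutrophil list had a median of 1.35 (camera adjusted p = 4.03e-05, and adjusted p = 0.263 with an estimated correlation). The B cell median was 1.20 (camera adjusted p = 3.44e-06, and adjusted p = 0.374 with an estimated correlation), and the T and NK cell median 0.66 (camera adjusted p = 3.44e-06, and adjusted p = 0.374 with an estimated correlation). Among 100 splits of the 10 arrays, 7, 13 and 15 gave as small a p for the neutrophil, B cell and T and NK cell lists. Within the lower and higher slide number ranges the medians were 1.32 and 0.89 for neutrophils and 1.25 and 0.90 for B cells. For T and NK cells they were 0.69 and 0.65. The higher range holds 1 p53-null array. The fixed slide block compares p53-null array 2 with wild-type array 4 alone. There the medians were smaller, at 0.59 for neutrophils, 0.43 for B cells and 0.36 for T and NK cells. With 1 p53-null array in either comparison, no pass or loss of a call was read from them. Red cell and platelet genes had a median of 0.52 (camera adjusted p = 0.197, but 0.81 and adjusted p = 0.0110 without p53-null array 2), with Itga2b at 1.28 ± 0.27, called in 3 of those 10 fits.

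**Figure D3:**
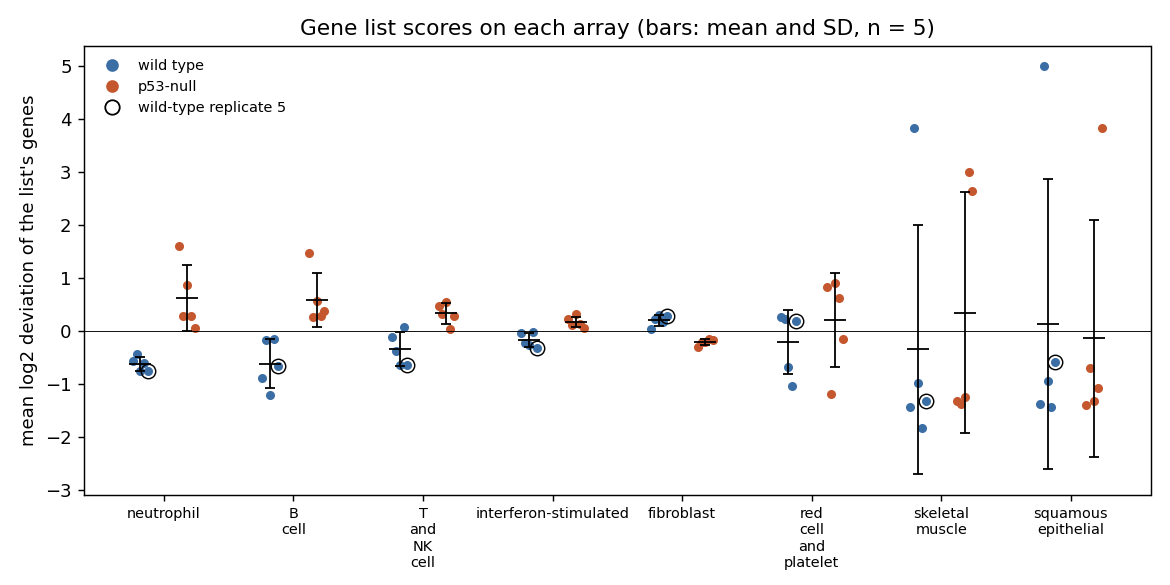
Mean log2 deviation of each list's genes from their mean over the 10 arrays; points are arrays, bars mean and SD (n = 5), and the ring marks wild-type replicate 5. Neutrophil, B cell and T and NK cell scores are higher in p53-null lung, and wild-type replicate 2 reads 4.99 for squamous epithelial genes.

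Some interferon-stimulated genes were also higher: 6 of 19 rose, 10 higher and 1 lower adjusted over the list alone, including Irf7 (1.04 ± 0.15), Oas1a (0.95 ± 0.10), Ifit3 (0.70 ± 0.15) and Usp18 (0.58 ± 0.089). The list's median was 0.31 (camera adjusted p = 7.26e-04, and adjusted p = 0.338 with an estimated correlation). The lower one, Ifit1, named after its values were seen, was at -0.48 ± 0.19. Ifit3 kept its call in 2 of the 10 fits that left out 1 array. As small a p was found in 13 of 100 splits of the arrays, and without wild-type array 5 the list did not pass (median 0.35, camera adjusted p = 0.137). With the slide as a fixed block, which rests on 1 array per genotype, the median was 0.23. Among cytokines and chemokines, secreted mediators of inflammation, 1 of 18 rose, the interleukin gene Il1b at 1.36 ± 0.22, and the list did not pass (camera adjusted p = 0.884). Mitotic and replication genes had 0 called members of 20 and a median of 0.26 (camera adjusted p = 0.0323, and adjusted p = 0.921 with an estimated correlation); Rrm2 differed by 0.54 ± 0.19 and Cenpa by 0.31 ± 0.12. For the mitotic list, 54 of 100 splits gave as small a p, and with the slide as a fixed block the median was 0.019.

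Some fibroblast genes and a few antioxidant genes were lower. The collagen genes Col3a1 (-0.94 ± 0.12) and Col1a2 (-0.82 ± 0.11), the matrix gene Npnt at -1.04 ± 0.20 and the growth factor receptor Pdgfra at -0.50 ± 0.13 made up the 4 of 10 fibroblast genes that fell, 5 adjusted over the list alone. A second Pdgfra probe differed by -0.005 ± 0.14, a second Col3a1 probe by -0.52 ± 0.33 and the other Npnt probes by -0.37 ± 0.14 and -0.32 ± 0.14. Pdgfra, Npnt and Gclc kept their call in 1, 3 and 3 of the 10 fits that left out 1 array. The fibroblast median was -0.37 (camera adjusted p = 6.91e-04, and adjusted p = 0.134 with an estimated correlation). Of 19 antioxidant genes 2 fell, 3 adjusted over the list alone: the extracellular superoxide dismutase Sod3 at -1.11 ± 0.12 and the glutathione synthesis enzyme Gclc at -0.60 ± 0.13. That list's median was -0.19 (camera adjusted p = 8.03e-04, and adjusted p = 0.263 with an estimated correlation), and 9 of 100 splits gave as small a p. With the slide as a fixed block, which rests on 1 array per genotype, the medians were -0.37 for fibroblast and -0.079 for antioxidant genes.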

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

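In groups of 5, a lowest or highest array was singled out where its gap to the nearest array exceeded Dixon's critical share of the range, which chance does in about 1 of 20 groups; 23 of 252 groups did so. The tests of probe GC content, foreign tissue, the label, blood and cell type shares were chosen after the result was seen. Among array measures these were outlier spots in wild-type array 3 (719, nearest 119), second component score in wild-type array 2 (-60.2, nearest 11.7) and second component score in p53-null array 5 (-56.2, nearest -0.0994). Among gene groups they were B cell markers in p53-null array 1 (1.47, nearest 0.57), skeletal muscle markers in wild-type array 2 (3.83, nearest -0.98), squamous epithelial markers in wild-type array 2 (4.99, nearest -0.59) and squamous epithelial markers in p53-null array 5 (3.83, nearest -0.69). Among genes they were Trp53 in wild-type array 5 (1.24, nearest 0.006), Cuedc1 in wild-type array 5 (-1.79, nearest -2.40), Ptprv in p53-null array 5 (-2.62, nearest -4.81), Psrc1 in wild-type array 1 (-1.92, nearest -2.24), Nfkb2 in wild-type array 5 (1.25, nearest 0.57), Nfkb2 in p53-null array 1 (1.53, nearest 1.17), Rrm2 in p53-null array 1 (-1.52, nearest -2.27) and Csf1r in wild-type array 5 (2.32, nearest 1.72). Further genes were Pax5 in p53-null array 1 (-1.67, nearest -2.44), Plvap in p53-null array 4 (4.64, nearest 4.40), Myh2 in wild-type array 2 (-1.66, nearest -5.18), Sprr1a in wild-type array 2 (0.86, nearest -2.02), Sprr1a in p53-null array 5 (-0.21, nearest -3.19), Krt5 in wild-type array 2 (3.69, nearest -0.90), Krt5 in p53-null array 5 (2.12, nearest -1.13) and Ddx3y in wild-type array 5 (0.19, nearest 1.23).

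The count of called genes rose from 1581 to 6619 when wild-type array 5 was left out. With the GC trend of probes removed, leaving it out still raised the count 4.09 times, which argues against that trend as the whole cause. Correlations of signal deviation with probe GC were 0.32 in wild-type array 5, 0.009 in wild-type array 2 and -0.29 to -0.21 in wild-type arrays 1, 3 and 4. On p53-null arrays they ran from -1.5e-06 to 0.19, so the trend ran partly with genotype. Skeletal muscle, squamous and heart genes, with median excesses of -1.14, -0.88 and 0.077 in wild-type array 5, argue against tissue of those kinds. Adipocyte genes stood 0.55 higher, below the limit of 1 log2 unit set for foreign tissue, and other tissues were not scored. By a rule added last, a p53-null mouse under this label is argued against. On genes chosen without it, wild-type array 5 lay on the wild-type side for 29.6% of chromosome 11 genes and 43.8% of p53 target genes. A p53-null array placed likewise did so for at most 11.5% and 6.25%. Earlier rules on its median position gave other outcomes. Its median position from wild type (0) to p53-null (1) was 0.893 on chromosome 11, 0.540 over 18 p53 target genes and 1.03 over all 6619 genes, with Psrc1 at 0.056 and Cdkn1a at 0.58, and why it lies near p53-null arrays for most genes, or whether it is of another genotype, stays open. Of 100 splits, 2 called as many genes as the real one: the real split and the one that exchanges wild-type array 5 with p53-null array 5, at 2671 against 1581.

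More genes were called near Trp53 than elsewhere, though the odds ratio without wild-type array 5 was 1.15 and did not pass, while each other array left out gave at least 1.87, which passed. With the GC trend removed from all 10 arrays the odds ratio was 1.57, past the threshold, so that trend does not account for it alone. Of 100 splits, 1, the real one, reached its Fisher p (−log10 p of 3.18, highest other 0.742), but no more than 2 of the others called enough genes to be able to, so the splits do not decide. Both groups are labelled C57BL/6J, but a donor-strain segment kept around the targeted gene is a candidate explanation. Among genes at 2-fold or more without wild-type array 5, such as Fbxo39, the odds ratio was 1.73 (interval 1.04 to 2.73). For calls of any size with all 10 arrays, a chromosome 5 window far from Trp53 had the highest share, 20.9%. At 2-fold or more with all 10 arrays, 39 of 1698 genes were called on chromosome 11 (2.30%) and 11 of 1284 on chromosome 5 (0.86%). The share called over all of chromosome 11, 11.5%, was close to the 12.2% within 10 Mb, so the excess was not confined to that window. It was uneven along the chromosome: no gene from 0 to 50 Mb was called at 2-fold or more, against 11 from 80 to 90 Mb. Within 20 Mb of Trp53 the odds ratio was 1.96 (Fisher's exact p = 2.14e-08). Effects of p53 itself on genes near Trp53 stay open and were not tested.

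Neutrophil, B cell and T and NK cell markers were higher in p53-null lung, and 3 of 3 lists still passed with the GC trend removed. A lower share of the lung's own cell types stays open: neutrophil, macrophage, B cell, T and NK cell and red cell and platelet scores differed between groups by amounts that spread over 1.11 (exact permutation p = 0.0476), but without macrophages, which live in lung, over 0.82 (exact permutation p = 0.198), and resident lists had medians from -0.37 to 0.084. More blood in the samples cannot be told apart, since red cell and platelet genes had a median of 0.52 and passed camera only without p53-null array 2. Chance could not be excluded: 7, 13 and 15 of 100 splits gave as small a p (−log10 p of 5.36, 6.61 and 6.66, highest other 6.40, 13.1 and 13.5). An effect of genotype stays open.

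For the other lists the splits with as small a p, the real one counted, numbered 4 for p53 target genes (−log10 p of 4.39, highest other 4.96) and 3 for fibroblast markers (3.91, highest other 4.06). Each share was under 0.05, the limit set beforehand. The splits that exceeded the real one each exchanged a single wild-type array with a single p53-null array, so they kept most of the genotype contrast. Adjusted over the 8 lists that had passed camera, of 28 tested, the shares were 0.160 and 0.160, so chance was not excluded. Chance was not excluded for interferon-stimulated genes, with 13 (3.81, highest other 8.99), antioxidant genes, with 9 (3.70, highest other 6.59), or mitotic genes, with 54 (2.03, highest other 21.9).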

How the results depend on the processing

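The GC trend removal, the set without 3 arrays and the set without chromosome 11 were chosen after seeing the data; the other alternatives were planned. No list, odds ratio or named gene past its threshold as reported turned direction in an alternative that gave a value. Of all 1581 called genes, 1556 kept their sign with the mean of all probes, 1576 with the slide as a fixed block, 1579 within the higher range, 1580 with the GC trend removed and wild-type array 5 left out. Lower calls outnumbered higher ones in the latter, within the lower range and without 3 arrays. With 0 calls there is no odds ratio. The cause of each change below was not tested, except that fewer arrays enter some fits. The slide as a fixed block compares p53-null array 2 with wild-type array 4. The higher number range compares p53-null array 2 with wild-type arrays 3 and 4. Counts, passes and losses in these fits rest on 1 p53-null array and decide nothing. Called, higher and lower genes were 1581, 970 and 611 in the fit as reported. With the median in place of the 75th percentile they were 583, 379, 204. With no filter on dim probes they were 538, 369, 169. With the slide as a fixed block they were 0, 0, 0. With the number range as a fixed block they were 697, 433, 264. With arrays of the lower number range alone they were 16, 5, 11. With arrays of the higher number range alone they were 0, 0, 0. With the scan day as a fixed block, which sets aside wild-type array 3 alone, they were 322, 214, 108. With the replicate block they were 26, 16, 10. With a trended, robust variance model they were 2253, 1281, 972. With array weights they were 6510, 3542, 2968. With adjusted p under 0.05 and at least 1.5-fold they were 800, 578, 222. With adjusted p under 0.01 they were 56, 35, 21. With the GC trend removed and wild-type array 5 left out they were 5921, 2687, 3234. With wild-type array 2 and p53-null arrays 4 and 5 left out they were 10, 4, 6. By limma the 0 calls with the slide as a fixed block and within the higher range stand beside 1133 and 2599 genes at an unadjusted p under 0.05. The results below no longer passed their threshold, given as log2 difference for Trp53 and median (fry: mean) for lists, except that cytokines passed only fry's mixed test. With quantile normalization, mitotic and replication genes 0.21. With the median in place of the 75th percentile, mitotic and replication genes 0.19. With the slide as a random block, mitotic and replication genes 0.25. With the slide as a fixed block, Trp53 -1.56, p53 target genes -0.073, interferon-stimulated genes 0.23, mitotic and replication genes 0.019, antioxidant and glutathione genes -0.079, T and NK cell markers 0.36, B cell markers 0.43, fibroblast markers -0.37. With the number range as a fixed block, mitotic and replication genes 0.20. With arrays of the lower number range alone, Trp53 -1.14. With arrays of the higher number range alone, where 1 p53-null array makes a pass unlikely, Trp53 -1.50, interferon-stimulated genes 0.18, mitotic and replication genes 0.13, B cell markers 0.90. With the scan day as a fixed block, mitotic and replication genes 0.19. With the replicate block, odds ratio near Trp53 4.06, Trp53 -1.28. With array weights, odds ratio near Trp53 1.13, interferon-stimulated genes 0.37, mitotic and replication genes 0.24. With the GC trend removed and wild-type array 5 left out, odds ratio near Trp53 1.08, interferon-stimulated genes 0.25, mitotic and replication genes 0.23. With wild-type array 2 and p53-null arrays 4 and 5 left out, Trp53 -1.37. With chromosome 11 left out, mitotic and replication genes 0.21. With an estimated correlation in camera, p53 target genes -0.21, interferon-stimulated genes 0.31, mitotic and replication genes 0.26, antioxidant and glutathione genes -0.19, neutrophil markers 1.35, T and NK cell markers 0.66, B cell markers 1.20, fibroblast markers -0.37. With fry, mitotic and replication genes 0.24. With fry's mixed test, cytokines and chemokines 0.12, mitotic and replication genes 0.24. Leaving out 1 array at a time gave these ranges: called genes 192 to 6619, lower genes 52 to 3015, mitotic and replication genes 0.13 to 0.31, higher genes 140 to 3604, odds ratio near Trp53 1.15 to 4.41, interferon-stimulated genes 0.28 to 0.37. Replicate numbers did not pair the arrays (correlations of same-numbered arrays -0.22 to 0.001), so the replicate block count of 26 says nothing of effect size. Of 59 named called genes such as Eda2r and Med1, 0 stayed called with the slide as a fixed block, 0 and 9 within the higher and lower ranges, 5 without the 3 arrays, 15 with the replicate block, 20 at adjusted p under 0.01, 38 with the scan day as a block, 33 to 59 with 1 array left out, and 43 to 59 in the other alternatives, with 42 of the 44 left once chromosome 11 was removed, and none turned. Of 59 genes called without the slide that holds both groups, 57 had the same sign within that slide, against 72.2% of all tested genes. Signal over background limits the dimmest genes, such as Mrgpra2b. The following, none past its threshold as reported, changed sign (median, fry: mean, for lists, log2 difference for genes). With normexp on mean and background signals, NF-kappaB feedback genes -0.00059. With quantile normalization, cytokines and chemokines -0.0092, alveolar type 2 markers -0.035, club and secretory cell markers -0.051, smooth muscle markers 0.016. With the median in place of the 75th percentile, cytokines and chemokines -0.011, pattern recognition and antimicrobial factors -0.049, NF-kappaB feedback genes -0.051, alveolar type 2 markers -0.013, club and secretory cell markers -0.0013. With genes kept only if well above background on all 10 arrays, squamous epithelial markers 0.015. With the mean of all probes of a gene, the mean over Trp53 probes (second probe as reported 0.31) -0.49, pattern recognition and antimicrobial factors -0.018. With the slide as a random block, smooth muscle markers 0.0076. With the slide as a fixed block, Satb1 -0.12, Hopx 0.059, Krt5 0.73, cytokines and chemokines -0.37, NF-kappaB feedback genes -0.16, immediate early and heat shock genes 0.16, circadian clock genes 0.063, macrophage markers -0.13, alveolar type 1 markers 0.12, smooth muscle markers 0.26, adipocyte markers -0.58, squamous epithelial markers 0.72. With the number range as a fixed block, sex-linked genes 0.043. With arrays of the lower number range alone, alveolar type 2 markers -0.025, ciliated cell markers -0.012. With arrays of the higher number range alone, Cidea -0.094, Krt5 0.15, cytokines and chemokines -0.25, pattern recognition and antimicrobial factors -0.025, NF-kappaB feedback genes -0.14, macrophage markers -0.043, alveolar type 1 markers 0.048, endothelial markers 0.17, smooth muscle markers 0.051, adipocyte markers -0.71, squamous epithelial markers 0.33. With the scan day as a fixed block, sex-linked genes 0.015. With array weights, smooth muscle markers 0.057. With the GC trend removed from each array, pattern recognition and antimicrobial factors -0.033, NF-kappaB feedback genes -0.0011, alveolar type 2 markers -0.076, club and secretory cell markers -0.055, sex-linked genes 0.020. With the GC trend removed and wild-type array 5 left out, pattern recognition and antimicrobial factors -0.045, NF-kappaB feedback genes -0.019, club and secretory cell markers -0.050. With wild-type array 2 and p53-null arrays 4 and 5 left out, NF-kappaB feedback genes -0.033, alveolar type 2 markers -0.055, club and secretory cell markers -0.042. With fry, pattern recognition and antimicrobial factors -0.020. With fry's mixed test, pattern recognition and antimicrobial factors -0.020. With 1 array left out at a time the ranges that crossed 0 were pattern recognition and antimicrobial factors -0.017 to 0.049, alveolar type 2 markers -0.081 to 0.16, adipocyte markers -0.077 to 0.39, sex-linked genes -0.20 to 0.061, Sprr1a -1.20 to 0.15, Krt5 -1.27 to 0.54, NF-kappaB feedback genes -0.023 to 0.044, smooth muscle markers -0.12 to 0.090, squamous epithelial markers -1.20 to 1.24, skeletal muscle markers -0.10 to 1.67.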

Other observations

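Other gene groups fixed before the data were examined did not pass camera in the fit with all 10 arrays. Median log2 differences were as follows: pattern recognition and antimicrobial factors 0.022 (adjusted p = 0.616), NF-kappaB feedback genes 0.019 (adjusted p = 0.913), apoptosis core genes 0.10 (adjusted p = 0.884), immediate early and heat shock genes -0.18 (adjusted p = 0.156), circadian clock genes -0.13 (adjusted p = 0.0657) and macrophage markers 0.18 (adjusted p = 0.559). Those of further groups were thymocyte markers 0.17 (adjusted p = 0.521), alveolar type 2 markers 0.058 (adjusted p = 0.726), alveolar type 1 markers -0.053 (adjusted p = 0.177), ciliated cell markers 0.084 (adjusted p = 0.695), club and secretory cell markers 0.069 (adjusted p = 0.826) and endothelial markers -0.18 (adjusted p = 0.0657). The last were smooth muscle markers -0.012 (adjusted p = 0.559), heart muscle markers 0.31 (adjusted p = 0.559), skeletal muscle markers 0.63 (adjusted p = 0.826), adipocyte markers 0.18 (adjusted p = 0.946), squamous epithelial markers -0.50 (adjusted p = 0.732) and sex-linked genes -0.030 (adjusted p = 0.695). Some passed in alternatives: endothelial markers in 4 of the 10 fits that left out 1 array and 5 of 22 others, circadian clock genes in 3 and 5, heart muscle and alveolar type 1 markers in 1 and 1 each, and immediate early and heat shock genes in 1 and 0. Within the higher slide number range, which holds 1 p53-null array, the adipocyte median had its sign turned, at -0.71. By fry's mixed test, which asks for change in either direction, 6 of these lists passed. Single members that passed were the heat shock gene Dnajb1 (-0.99 ± 0.22, adjusted p = 0.0311), the macrophage genes Car4 (0.53 ± 0.10), Marco (-0.77 ± 0.17) and Csf1r (0.56 ± 0.14), the endothelial gene Plvap (-0.40 ± 0.087, adjusted p = 0.0297), the ciliated cell gene Tekt1 (0.38 ± 0.10, adjusted p = 0.0499) and the apoptosis gene Bad (0.45 ± 0.12, adjusted p = 0.0498). Csf1r, Tekt1, Bad, Marco, Plvap, Car4 and Dnajb1 kept their call in 1, 1, 1, 3, 3, 4 and 4 of the 10 fits that left out 1 array, and a further Csf1r probe differed by -0.11 ± 0.18 and a further Tekt1 probe by 0.81 ± 0.12. Members with the smallest p that did not pass were Tlr4 (-0.38 ± 0.13), Nod2 (-0.45 ± 0.16), Nfkb2 (0.56 ± 0.17), Relb (0.28 ± 0.11), Clock (-0.39 ± 0.12), Cry1 (-0.73 ± 0.22), Cd1d1 (0.32 ± 0.10) and Satb1 (0.37 ± 0.15).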
